A study of Mus musculus with 6 samples.

How the data were processed

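Spleen RNA from 2 groups of mice was measured on 6 Illumina MouseRef-8 v2 expression arrays, 3 from mice labelled as Rag2/pfp knockout and 3 from mice labelled as wild type. Rag2 encodes a subunit of the recombinase that assembles antigen receptor genes, and pfp is the older name of Prf1, the gene of perforin. Per the labels' protocols, total RNA was purified on columns, 500 ng was reverse transcribed with an oligo(dT) primer that carries a T7 promoter, and biotin-labelled cRNA was hybridised. Such a primer labels transcripts from their 3' ends. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the samples of a group came from separate animals. The p-values of the probe tests therefore measure only the spread between these samples, which may be technical in part. Knockout replicate 2 differed from replicates 1 and 3 in Xist and Eif2s3y, so the spread of that group is not technical alone.

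The authors deposited a table of signal intensity, the mean bead brightness of each probe on a linear scale, not normalized between arrays, per the file headers. Each intensity column is followed by a detection p-value per probe, per the file headers, which sets the probe against the array's negative control beads. GenomeStudio 2011.1 is named in the submitters' processing notes, and other settings are not given in the sources used here. A second table deposited by the authors holds log2 values whose method is not stated. Set against the raw signal, it matched quantile-normalized log2 signal without background correction to within 5e-07 on every probe, so its scale is known. The median of each of its 6 columns was 7.24, and its genes were not centred.

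The raw intensities were background corrected and normalized with neqc in limma 3.58.1 (R 4.3.3). This fits a normal-exponential model with the negative control level inferred from the detection p-values, adds an offset of 16, quantile-normalizes between arrays and takes log2. Differences are therefore on the log2(value + offset) scale, which understates the change of weakly expressed genes. Quantile normalization gives every array the same distribution, so a shift of most transcripts in 1 direction is removed. A probe was tested when its detection p-value was under 0.05 on at least 3 of the 6 arrays, which left 12885 of 25697 probes. A linear model with group as the only term was fitted with lmFit and eBayes, which uses a two-sided moderated statistic. Probes were called at a Benjamini-Hochberg adjusted p under 0.05. The number of arrays, 3 per group, limits the precision.

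Gene symbols came from the platform's annotation table and were updated by gene number or accession against a RefSeq gene table of assembly GRCm38.p6. Of the 25697 probes, 23978 had 1 symbol, 0 had several and 1719 were unnamed here. Gene numbers matched 23962 probes and accessions matched another 9, and 8 symbols were updated. The files name no genome build, so no coordinates are given. A gene was represented by its tested probe with the highest mean, which gave 9158 genes. Of 2223 genes with more than 1 tested probe, 118 had a called probe, 43 of these had all probes called the same way and 0 had probes called in opposite directions.

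A probe with a detection p-value of 0.05 or more on all 3 arrays of a group has only a bound there. Its change is given as at least N-fold, the mean of the other group against the mean, per array, of the higher of the probe's own value and the lowest normalized value among detected probes. The fit's adjusted p is given beside it. Such bounds hold for background-corrected values, since without that correction the differences of the named genes concerned were smaller.

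Before the data were examined, 26 gene lists were fixed for cell types of the spleen, tissues that could be dissected with it and pathways. Some genes stand in more than 1 list, such as Alas2, Gata2, Nkg7 and the C1q genes. Lists with at least 3 tested genes, 24 in all, were tested with camera in limma with a preset correlation of 0.01, adjusted over the lists. With that preset, camera sets a list's genes against all other genes, so its p-values measure mainly the spread between genes. They hardly reflect shifts that a list's genes share on an array. The correlation estimated from the data and fry were alternatives. Gene names in the text follow a rule fixed at the same time. It takes the targeted genes, the 8 genes with the largest increase and the 8 with the largest decrease among called genes, without clone-type names. From each list it takes up to 3 called members with the largest change, or the 2 tested members with the highest mean where fewer than 2 were called. Members named outside this rule are said to be so.

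Alternatives were no between-array normalization, median centring, cyclic loess, no background correction, the authors' log2 values, 3 other detection filters, another variance model, array weights, the replicate number as a block, each array left out in turn, a stricter adjusted p and the mean over a gene's probes in the list tests. Array brightness as a covariate was added after seeing the data. The fit was tested on simulated data for the knockout against wild-type comparison, with the means and spreads of the 12885 tested probes, 200 changed probes and 20 simulations. It recovered 9.45% of probes changed by 1 log2 unit and 68.2% of those changed by 2 log2 units, and 3.60% of calls were false. Changes near 2-fold were thus mostly missed in such data. The simulated probes varied independently, with the same spread in both groups. The real arrays share deviations across probes, so these shares may not hold for them.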

Results

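Gene expression was profiled in the spleens of mice labelled as Rag2 and perforin knockouts and in wild-type spleens, with 3 arrays per group, to ask how loss of these genes alters the spleen transcriptome. Each array carried 25697 probes. Between 12084 and 12595 probes were detected on the knockout arrays and between 12545 and 13149 on the wild-type arrays. The median raw signal was 158, 142 and 144 on knockout replicates 1 to 3 and 164, 151 and 151 on wild-type replicates 1 to 3. Across probes, which are not independent replicates, normalized values of wild-type arrays correlated at 0.978 to 0.987 and those of knockout arrays at 0.931 to 0.958. Knockout replicate 2 stood apart in Xist, the transcript of the inactive X chromosome. Its 2 probes were not detected there, at 4.88 and 5.13 log2, and lay at 7.13 to 9.41 on the other 5 arrays.

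The targeted genes were examined first. The Rag2 probe was not detected on any of the 6 arrays, with 4.74 ± 0.14 log2 in the knockout and 4.66 ± 0.03 in wild type (SD, n = 3), so it gave no check of the genotype. Prf1, which encodes the pore-forming protein of cytotoxic granules, was detected on all 6 arrays by 2 probes. Its brighter probe read 11.48 ± 0.54 log2 in the knockout and 11.14 ± 0.36 in wild type (SD, n = 3), a difference of 0.34 ± 0.32 (SE) that did not pass the limma test (adjusted p = 0.670). The other probe differed by 0.42 ± 0.31 (adjusted p = 0.544). Where these probes lie relative to the disrupted part of the gene is not known here, so Prf1 signal does not check the labels either.

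Transcripts of B cells, T cells and plasma cells made up the deepest losses in the knockout spleen, while the increases were fewer and smaller. Of 12885 tested probes, 505 were called, 126 higher and 379 lower in the knockout, and 498 of them changed at least 2-fold. By gene, 95 were higher and 264 lower among 9158, and 207 of the lower genes were in none of the lists. The knockout and wild-type values did not overlap on 3148 of the 12885 tested probes, or 24.4%, against 10% by chance with 3 against 3 values. Of the called genes, 43 were not detected on any knockout array and 6 on no wild-type array. The split into higher and lower calls moved with the scaling, to 16 higher and 857 lower without between-array normalization and to 49 and 661 with median centring, where the median of all tested probes lay at -0.33 and -0.16. Leaving out wild-type replicate 1, 2 or 3 reduced the calls to 166, 169 or 188.

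All 18 tested B cell genes fell, with a median difference of -4.07 log2 (camera adjusted p = 3.24e-41, and adjusted p = 0.0232 with an estimated correlation). The count was also 18 adjusted over the list alone. Fcmr, the Fc receptor for IgM, read 13.40 ± 0.03 log2 in wild type (SD, n = 3) and was not detected on any knockout array, where it read 4.97 to 5.04, at least 248-fold lower (adjusted p = 1.77e-07). This size depends on the background correction, without which Fcmr differed by -6.30 log2. Pou2af1, a B cell transcriptional coactivator, fell by 6.40 ± 0.27 log2 (SE) and was detected on 1 knockout array. Cd79a, a signalling chain of the B cell receptor, fell by 6.16 ± 0.48. The kinase gene Blk fell by 5.41 ± 0.32, with its 2 other tested probes called lower as well. Over the alternatives the smallest differences of these genes were -4.62 log2 for Pou2af1, -4.69 for Cd79a and -4.11 for Blk. All 8 plasma cell genes fell, also when adjusted over the list alone, with a median of -3.15 log2, or -2.89 with undetected genes at their bound (camera adjusted p = 5.38e-16, and adjusted p = 0.0232 with an estimated correlation). Mzb1, a chaperone of immunoglobulin-secreting cells, fell by 6.69 ± 0.33 log2. Tnfrsf17, the receptor BCMA, was at least 10.1-fold lower and Derl3, of the endoplasmic reticulum degradation machinery, at least 7.16-fold lower, with neither detected on a knockout array. Without background correction they differed by -2.16 and -1.73 log2.

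Of 19 tested T cell genes, 12 fell and 7 did not pass, and 14 fell when adjusted over the list alone. The median was -2.53 log2, or -2.21 with undetected genes at their bound. Camera called the list (adjusted p = 2.09e-23), and the call was lost at adjusted p = 0.0688 with an estimated correlation. Cd3e, a chain of the T cell receptor complex, was at least 49.0-fold lower (adjusted p = 3.14e-06), from 11.07 ± 0.26 log2 in wild type to 5.01 ± 0.13 (SD, n = 3). The surface receptor gene Cd6 was at least 41.2-fold lower, with its 2 other tested probes called lower too, and Cd3g fell by 5.33 ± 0.23 log2 (SE). Without background correction Cd3e differed by -4.02 and Cd6 by -3.70 log2. The smallest difference of Cd3g over the alternatives was -3.68 log2.

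**Figure D1:**
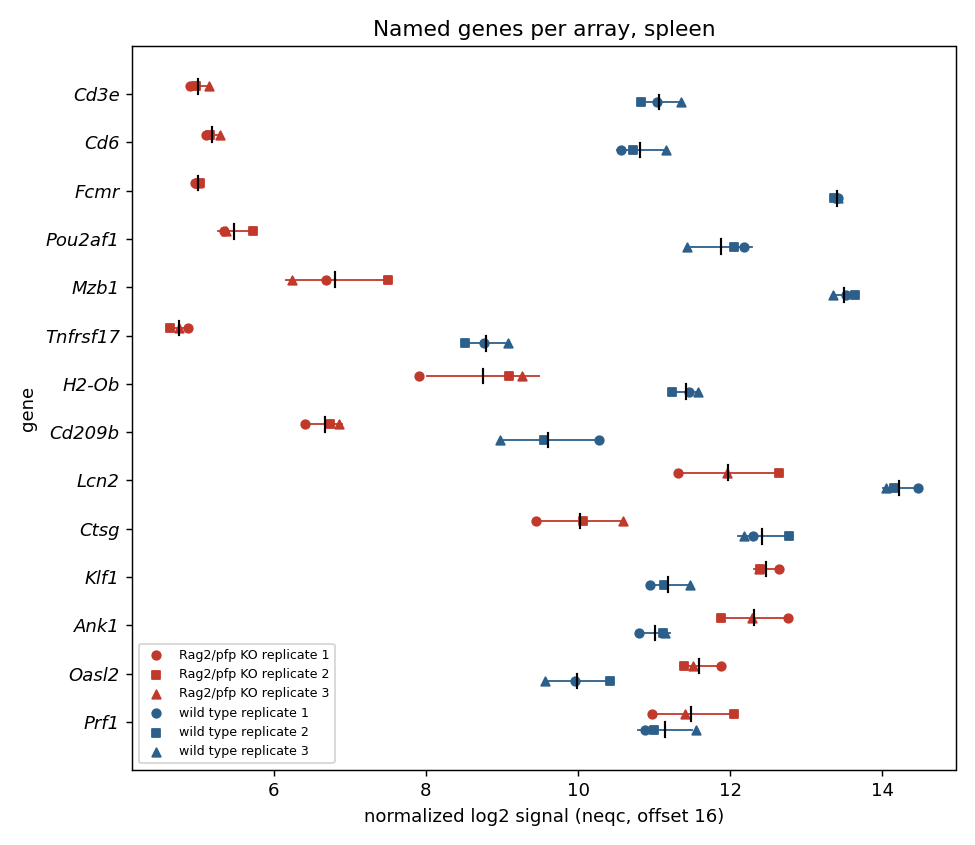
Normalized log2 signal (x axis) of 14 named genes (y axis) on each array, with red for Rag2/pfp knockout and blue for wild type, marker shape for the replicate, a black tick for the group mean and a line for the mean ± SD (n = 3). Cd3e read 5.01 in the knockout and 11.07 in wild type on average, whereas the knockout and wild-type values of Prf1 overlapped.

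Genes of MHC class II antigen presentation had a median of -0.62 log2 over 10 tested members, of which 2 fell, also when adjusted over the list alone. H2-Ob fell by 2.67 ± 0.36 log2 (SE), and H2-DMb2 fell by 2.25 ± 0.27. H2-Ob encodes a chain of H2-O, a modulator of peptide loading known from B cells, and H2-DMb2 a chain of the peptide-loading factor H2-M. The list was called lower (camera adjusted p = 6.22e-04), with adjusted p = 0.434 with an estimated correlation and adjusted p = 0.0607 without knockout replicate 1. The mean of the list relative to wild type was -1.54 on knockout replicate 1, -0.26 on replicate 2 and -0.84 on replicate 3. White pulp stroma and chemokine genes had a median of -0.87 log2 (-0.81 with undetected genes at their bound), and 2 of 14 fell, or 6 adjusted over the list alone (camera adjusted p = 4.42e-05, and adjusted p = 0.391 with an estimated correlation). These were Ccl21a, at -2.20 ± 0.48 log2, and Ccl21b, at -2.23 ± 0.50, near-identical genes of a T zone chemokine whose probes may not be told apart. Their calls were lost without knockout replicate 1 or 3, without any wild-type replicate, without background correction and without the detection filter, with adjusted p up to 0.156 and 0.159 over the alternatives. This list also stood lowest on knockout replicate 1, at -1.74 against -0.37 and -0.81. It also holds the cytokine genes Lta, Ltb, Tnf, Tnfsf11 and Tnfsf13b, named after their values were seen, so its fall need not be one of stroma. Ltb, at -1.96 ± 0.50 log2, and Lta, at -1.15 ± 0.35, differed most among them, and none of them was called over all probes.

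Natural killer cell genes had a median of 0.51 log2 over 15 tested members, 13 of them above 0. None was called over all probes, and 6 were called higher adjusted over the list alone. Camera called the list higher (adjusted p = 8.76e-04), with adjusted p = 0.391 with an estimated correlation. The list mean relative to wild type was 0.13 on knockout replicate 1 and 0.93 and 0.66 on replicates 2 and 3. Its brightest members differed by -0.64 ± 0.37 log2 for Nkg7, a granule protein gene (adjusted p = 0.434), and by 0.24 ± 0.26 for the chemokine gene Ccl5 (adjusted p = 0.707). Cytotoxic granule genes had a median of -0.33 log2 over 10 members and were not called as a list (camera adjusted p = 0.0525). The list was called lower in 5 alternatives, among them without knockout replicate 2 (adjusted p = 0.0171) and with array brightness as a covariate (adjusted p = 0.0186). Gzmm, which encodes granzyme M, was the 1 member that fell, also adjusted over the list alone, by 1.28 ± 0.26 log2, and is named after its values were seen. Lamp1 differed by -0.28 ± 0.22 log2 and Ctsc, the protease that activates granzymes, by -0.36 ± 0.29. None of 6 tested genes of V(D)J recombination and DNA end joining was called, also adjusted over the list alone (median 0.15 log2, camera adjusted p = 0.631). Xrcc6, which encodes Ku70, differed by 0.34 ± 0.22 log2 and Hmgb2 by 0.50 ± 0.35.

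Neutrophil and granulocyte precursor genes were lower in the knockout, with 10 of 16 called lower, 13 adjusted over the list alone, and a median of -1.55 log2. The list was called (camera adjusted p = 3.48e-13), with adjusted p = 0.313 with an estimated correlation. Ctsg, which encodes cathepsin G, fell by 2.39 ± 0.33 log2 (SE). Ngp, neutrophilic granule protein, fell by 2.33 ± 0.36, and Lcn2, lipocalin 2, fell by 2.25 ± 0.34. The call of Ngp was lost without wild-type replicate 1 and without the detection filter, with adjusted p up to 0.0519. The list mean relative to wild type was -2.20, -1.15 and -1.24 on knockout replicates 1 to 3.

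Macrophage genes had a median of -0.26 log2 over 17 tested members, 2 of which fell, also adjusted over the list alone (camera adjusted p = 0.0312, and adjusted p = 0.563 with an estimated correlation). Cd209b, a lectin of marginal zone macrophages, fell by 2.93 ± 0.33 log2, with its 2 other tested probes called lower as well. Timd4, a phosphatidylserine receptor, fell by 1.28 ± 0.27, a call lost without any single wild-type replicate, without background correction and without the detection filter (adjusted p up to 0.192). Monocyte genes had a median of -0.43 log2, with 2 of 9 lower, or 3 adjusted over the list alone (camera adjusted p = 0.0285, and adjusted p = 0.545 with an estimated correlation). Lyz2, lysozyme, fell by 1.61 ± 0.30 log2, although its other probe, at -0.80 ± 0.38, was not called (adjusted p = 0.324). Ly6c1, which has a near-identical neighbour in Ly6c2, fell by 1.45 ± 0.28 log2. Both genes lost their calls without wild-type replicate 1 or 2, at adjusted p up to 0.102 for Lyz2 and 0.132 for Ly6c1. Without knockout replicate 1, knockout replicate 3 or wild-type replicate 1, the macrophage list had adjusted p = 0.139, 0.0553 and 0.293 and the monocyte list 0.183, 0.0634 and 0.0831. The macrophage median relative to all tested genes was 0.02 without wild-type replicate 1. Both calls were also lost without between-array normalization, with median centring and with array weights. Neither dendritic cell genes (median 0.48 log2 over 8, camera adjusted p = 0.463) nor mast cell and basophil genes (median -0.26 over 6, camera adjusted p = 0.661) were called, and none of their members passed, also adjusted over the list alone. Irf8 differed by -0.35 ± 0.33 log2, Batf3 by 0.60 ± 0.45, Hdc by -0.98 ± 0.42 and Gata2 by 0.40 ± 0.32.

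Erythroid genes had a median of 1.01 log2, with 17 of 18 above 0, 3 called higher and 10 called higher adjusted over the list alone. Camera called the list (adjusted p = 9.84e-08), with adjusted p = 0.313 with an estimated correlation. Ank1, the red cell ankyrin, rose by 1.30 ± 0.28 log2 (SE), with its 3 other tested probes called higher too, the erythroid transcription factor gene Klf1 rose by 1.28 ± 0.24, and the erythropoietin receptor gene Epor by 1.25 ± 0.29. Each of these 3 calls was lost without wild-type replicate 1, 2 or 3 and without between-array normalization, with adjusted p up to 0.190, 0.129 and 0.211. The list mean relative to wild type was 1.47 on knockout replicate 1 and 0.67 and 0.65 on replicates 2 and 3. Heme synthesis genes had a median of 0.73 log2, with all 8 above 0, 0 called over all probes and 7 higher adjusted over the list alone (camera adjusted p = 5.91e-05, and adjusted p = 0.335 with an estimated correlation). This list also stood highest on knockout replicate 1, at 1.501 against 0.655 and 0.586. Urod differed by 0.74 ± 0.23 log2 and Alas2, the erythroid enzyme of the first step, by 0.71 ± 0.22. Megakaryocyte and platelet genes had a median of 0.79 log2, with all 11 above 0, 0 called and 5 higher adjusted over the list alone (camera adjusted p = 1.10e-04, and adjusted p = 0.335 with an estimated correlation). Treml1 differed by 0.82 ± 0.28 log2 and Ppbp by 0.53 ± 0.41.

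Cell cycle genes had a median of 0.78 log2, with all 15 above 0, 1 called higher and 6 higher adjusted over the list alone (camera adjusted p = 1.11e-06, and adjusted p = 0.376 with an estimated correlation). The called member, named after its values were seen, was Mcm7, a subunit of the replicative helicase, which rose by 1.55 ± 0.33 log2. The brightest members, Mcm5 and Mcm4, differed by 0.57 ± 0.23 and 0.54 ± 0.31 and were not called. The list mean was 1.36 on knockout replicate 1 and 0.61 and 0.45 on replicates 2 and 3. Haematopoietic stem and progenitor genes were not called (median 0.34 log2 over 5, camera adjusted p = 0.274), with Meis1 at 0.15 ± 0.38, and 0 members were called adjusted over the list alone.

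Interferon-stimulated genes had a median of 0.75 log2 over 13 members, with 2 called higher and 6 adjusted over the list alone (camera adjusted p = 4.94e-04, and adjusted p = 0.376 with an estimated correlation). Oasl2, an oligoadenylate synthetase-like gene, rose by 1.61 ± 0.28 log2, although its other probe, at 1.07 ± 0.53, was not called (adjusted p = 0.345). Rtp4 rose by 1.29 ± 0.23. Both calls were lost without wild-type replicate 1 or 3 and without between-array normalization, with adjusted p up to 0.0847 and 0.173. No member of the fibroblast (median -0.11 log2 over 17, mean 0.00, camera adjusted p = 0.962), endothelial (-0.10 over 14, adjusted p = 0.680), complement (-0.04 over 9, adjusted p = 0.775) or ribosomal protein list (-0.19 over 19, adjusted p = 0.129) was called, also adjusted over the list alone. The ribosomal protein list was called lower in 4 alternatives, with adjusted p down to 0.0327. The fibroblast median and mean differed in sign. Acta2 differed by -0.14 ± 0.30 log2, Bgn by -0.11 ± 0.32, Plvap by -0.21 ± 0.36, Egfl7 by 0.06 ± 0.33, C1qb by -0.26 ± 0.36, C4b by 0.02 ± 0.51, Rplp1 by -0.19 ± 0.21 and Rps20 by -0.03 ± 0.23. Immediate early and heat shock genes had a median of 0.28 log2 over 11 members (camera adjusted p = 0.531), with 0 called and, adjusted over the list alone, 1 higher and 1 lower. Zfp36 differed by -0.78 ± 0.22 log2 and Dnajb1 by 0.54 ± 0.25. Among markers of adjacent tissues, 2 acinar pancreas genes were tested, Cela1 at 0.47 ± 0.22 log2 and Ctrl at -0.10 ± 0.30, and 1 fat gene, Lep, at 0.19 ± 0.25, none of them called, also adjusted over the list alone.

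**Figure D2:**
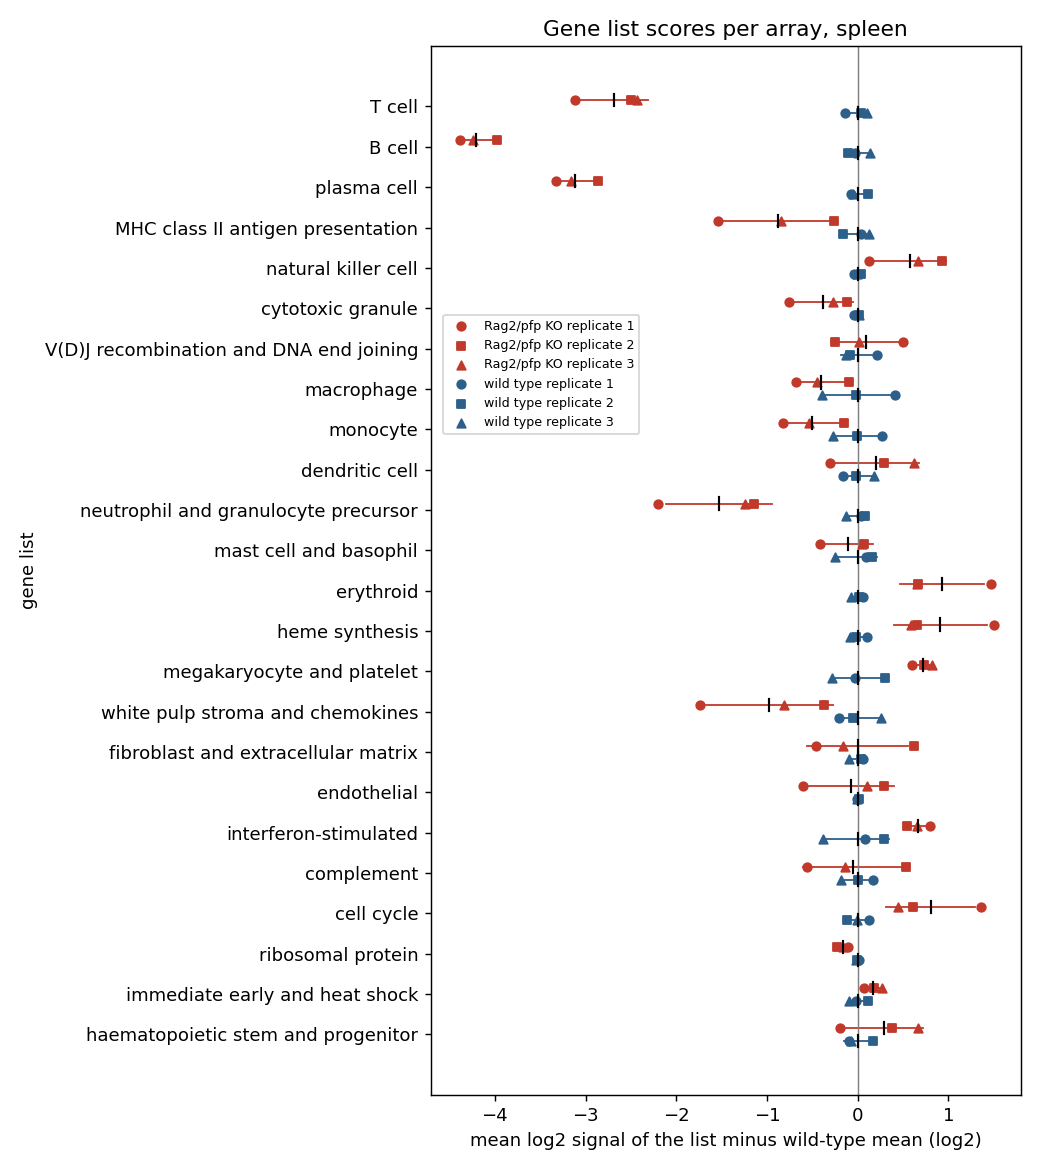
Mean normalized log2 signal of each list's tested genes minus the wild-type mean (x axis) for the 24 tested lists (y axis) on each array, with red for Rag2/pfp knockout and blue for wild type, marker shape for the replicate, a black tick for the group mean and a line for the mean ± SD (n = 3). The B cell list lay between -4.39 and -3.98 on the knockout arrays, and the erythroid list between 0.65 and 1.47.

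The gene with the largest increase was Tmem87a, which encodes a membrane protein. It read 8.72 ± 0.43 log2 in the knockout and was not detected on any wild-type array, where it read 4.97 ± 0.05 (SD, n = 3), at least 10.4-fold higher (adjusted p = 6.13e-05). Without background correction Tmem87a differed by 1.97 log2, still called. The kinase gene Stk35 rose by 2.23 ± 0.31 log2 (SE), and by 1.01 to 2.58 over the alternatives. Klrb1b, a lectin-like receptor of natural killer cells in a family of similar genes, rose by 2.09 ± 0.39. Of its 2 other tested probes, 1 was called higher and the other, at 1.32 ± 0.32, was not (adjusted p = 0.0552). The catalase gene Cat rose by 1.99 ± 0.43 log2, Rcc1 by 1.78 ± 0.28, Mboat2 by 1.78 ± 0.28, Sec14l2 by 1.76 ± 0.30 and the globin gene Hbq1b by 1.65 ± 0.24. The other probe of Mboat2, at 1.26 ± 0.35, was not called (adjusted p = 0.0880). Tmem87a and Stk35 were called under all alternatives. The other 6 lost the call without wild-type replicate 1. Adjusted p over the alternatives reached 0.119 for Klrb1b, 0.157 for Cat, 0.0562 for Rcc1, 0.0552 for Mboat2, 0.0979 for Sec14l2 and 0.0562 for Hbq1b. Their differences went down to 0.94 log2 for Klrb1b, 1.48 for Cat and 1.37 for Rcc1. They went down to 1.14 for Mboat2, 1.10 for Sec14l2 and 0.70 for Hbq1b.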

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

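The search for this signal and its test were chosen after the data had been seen. Among probes outside the tested set, the Y-linked gene Eif2s3y stood out because 1 knockout array lay more than 3 log2 units above every wild-type array. It read 8.30 log2 on knockout replicate 2, against at most 4.82 on the wild-type arrays, and was detected on that array alone. The same array was the one without detected Xist. A male mouse may account for both, in which case the knockout group mixed sexes. Of 15 probes of other genes on the Y chromosome in assembly GRCm38.p6, 3 were detected on this array and at most 1 on any other. As most of them lay at background on all arrays, this count cannot decide the sex of this mouse, which the labels do not give. Xist and Eif2s3y both set this array apart from every other, and both go with a male mouse. Without knockout replicate 2, 678 probes were called, 205 higher and 473 lower.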

How the results depend on the processing

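Array brightness, the median raw signal of each array, was chosen as a covariate after seeing the data, and the other settings were planned. Without between-array normalization 873 probes were called, 16 higher and 857 lower, 854 of them at least 2-fold. Median centring gave 49 higher and 661 lower. Without background correction, and with the authors' log2 values, 277 and 277 probes were called with at least 2-fold change. No detection filter left 78 higher and 287 with at least 2-fold change, with more probes tested. Array weights gave 790 calls, 257 higher. Array brightness as a covariate gave 1275, with 560 higher, 715 lower and 1192 at least 2-fold. An adjusted p under 0.01 left 166. The cause of these shifts was not tested.

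With the replicate number as a block, 887 probes were called, 316 higher and 571 lower, 872 of them at least 2-fold. Deviations from the group means correlated at 0.50, -0.28 and -0.04 between arrays of the same number, so the number by itself does not mark matched arrays. Arrays of different numbers reached 0.50 for knockout replicate 3 with wild-type replicate 2 and 0.48 for knockout replicate 2 with wild-type replicate 3. Only 1 of the 3 knockout arrays correlated best with its own number. Each knockout array thus had a wild-type array at 0.48 to 0.50, and what such arrays share was not tested.

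With 1 array left out, calls ranged from 166 to 678, higher calls from 7 to 205, lower calls from 158 to 473 and calls with at least 2-fold change from 166 to 674. Wild-type replicates 1, 2 and 3 gave 166, 169 and 188 calls when left out, with fewer samples in the fit, and knockout replicate 2 gave 205 higher calls. The fibroblast list, not called in the main comparison, was called lower without knockout replicate 2 (median -0.38 log2, relative to all tested genes, adjusted p = 0.0497). Its median ranged up to 0.12 without knockout replicate 3.

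With an estimated correlation 2 gene lists were called, the B cell and plasma cell lists, against 14 with the preset correlation. Fry called 7, the B cell, plasma cell, T cell, neutrophil, erythroid, heme synthesis and ribosomal protein lists. The ribosomal protein list (fry adjusted p = 0.0338) was not called by camera. Fry did not call the MHC class II, natural killer, macrophage, monocyte, megakaryocyte, white pulp, interferon-stimulated or cell cycle lists, with adjusted p from 0.0515 to 0.252. The B cell and plasma cell lists were called under all alternatives run. Of the 34 called named genes, 17 were called under all alternatives, and 91 of 612 values of called genes and 34 of 294 of called lists lost the call. None of these called results reversed in its test. The tallies count no background correction and the authors' log2 values as 2 alternatives, although they hold the same values to within 5e-07. Another 22 uncalled values became called, and 48 uncalled values changed sign without being called, which was not counted as a change. The slide as a block was not run because no slide is given in the sources used here. Signal over background limits weak genes, and 12812 probes below the detection filter were not tested.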

Other observations

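The gene groups outside the lists, the comparisons between lists, the fit with array brightness and the tests on neighbouring genes in this part were chosen after the data had been seen. Of the 359 called genes, 296 were in none of the lists, 89 higher and 207 lower. Of 7 tested Gimap genes, GTPases of lymphocytes that were not tested for enrichment, 6 were called lower, and the median was -2.04 log2. Gimap5, at -1.02 ± 0.44 log2 (SE), was not called (adjusted p = 0.265). All 7 were below 0, and 6 or 7 were called lower, under the 3 other scalings. Gimap7 fell by 2.72 ± 0.36 log2 (SE) and Gimap1 fell by 2.28 ± 0.29. Ctla4 and Foxp3, genes known from regulatory T cells, fell by 2.31 ± 0.26 and 1.31 ± 0.26. Among called genes that rose outside the lists were Gfi1b, a transcription factor of erythroid and megakaryocytic cells, at 1.29 ± 0.26, and the red cell membrane genes Dmtn at 1.37 ± 0.25, Icam4 at 1.48 ± 0.33 and Add2 at 1.17 ± 0.26. E2f1 and Uhrf1, known from S phase entry and DNA methylation maintenance, rose by 1.15 ± 0.25 and 1.03 ± 0.23. These risen genes were picked by name from the 89, and the alternatives were not run for them. Over all tested probes, higher calls fell to 7, 11 and 21 without wild-type replicates 1, 2 and 3.

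The real grouping called 505 probes, and the highest of the other splits of the 6 arrays into 3 and 3 called 0 with limma, with at most 1156 at an unadjusted p under 0.05. As 1 of 10 splits gave as many, the splits are too few for a share under 0.05.

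The erythroid list was called higher by camera, with 3 of 18 genes called, but not with an estimated correlation (adjusted p = 0.313). Fry called it at adjusted p = 0.0427. In the simplest case lymphocytes are lost and all other cells stay unchanged, so the transcripts of every remaining cell type would rise alike. Other cells need not stay unchanged, as Cd209b in the macrophage list stood at -2.93 ± 0.33 log2 (SE). Differences between lists therefore bear only on this simplest case, not on lymphocyte loss with other cells changed too. The erythroid list changed by 1.33 ± 0.46 log2 (SE) more than the macrophage list and the neutrophil list by 1.12 ± 0.29 less. However, the erythroid excess over the endothelial list, 0.996 ± 0.539, was within 2 SE. The megakaryocyte and natural killer lists exceeded the macrophage list too, by 1.13 ± 0.27 and 0.98 ± 0.26. By these SEs the lists did not all change alike. A rise that the erythroid list shares with the megakaryocyte and natural killer lists stays open. An exact permutation test of these differences cannot go below p = 0.10 (two-sided). Array brightness as the cause is argued against by the fit that includes it. There the erythroid median was 1.32 log2 and 10 members were called higher. The size of that median is uncertain, since knockout replicate 1 was both the brightest knockout array and the highest in this list. The same fit raised the calls over all tested probes to 1275. A larger erythroid share in the knockout spleen may account for the pattern and remains open as an untested hypothesis.

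Targeted alleles made in one strain and bred into another can carry donor DNA around the gene, so genes near Rag2 and Prf1 in assembly GRCm38.p6 were examined. Among the 100 nearest tested genes, 25 on each side of each gene, 3 were called, against a 95th percentile of 8 in 10000 random pairs of windows. They were Cat, at 1.99 ± 0.43 log2 (SE), and Ddb2, at -1.01 ± 0.22, near Rag2, and Chst3, at -4.83 ± 0.28, near Prf1. With 100 genes on each side, 13 of 200 were called around Rag2 and 9 of 200 around Prf1, against 359 of 9155 overall. These wider windows were not set against random ones, and the 13 around Rag2 include the 7 called genes of the run described in the next paragraph. The count of 3 leaves donor DNA open, since such DNA may alter few genes, and a count within the random range excludes nothing.

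Tmem87a lies on the chromosome of Rag2, with 68 tested genes between them, in a window of 25 tested genes of which 7 were called. Windows with 7 calls stood on 3 chromosomes, and shuffled calls reached that count with p = 0.069 (permutation, one-sided), so chance placement may account for the run. Within it Tmem87a, not detected on any wild-type array, was at least 10.4-fold higher (a fitted difference of 3.75 log2, which is no bound, and 1.97 without background correction). Loss of lymphocyte transcripts was taken to leave Tmem87a level or lower, and it rose instead. This prediction left out a relative rise of the transcripts of remaining cells. However, Tmem87a was picked as the largest increase. Its rise was larger than any list median, none of which rose above 1.01 log2. Stk35, also picked for its large increase, rose by 2.23 ± 0.31, and the cause of that rise is not known either. A single gene picked in this way does not decide whether lymphocyte loss had a part. Of the 6 that fell, such as Ell3, 0 are in a list of another cell type and 0 have another tested probe. They are in none of the lymphocyte lists either, so the lists do not say which cells transcribe them. Lymphocyte loss and a sequence variant under single probes thus cannot be told apart there. A strain difference at Tmem87a remains a candidate explanation and was not tested.

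The Mid1 probe read 11.02 log2 on wild-type replicate 1 and 6.67 on replicate 3, against 4.84 to 5.26 on the other 4 arrays. The fat gene Adipoq read 7.84 on wild-type replicate 2, against at most 5.59 on the others.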
